A study of Mus musculus with 6 samples.

How the data were processed

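RNA was measured on 6 Affymetrix mouse expression arrays, with biotin-labelled target made from total RNA, per the labels' protocols. The cells came from a mouse embryonic stem (ES) cell line in which doxycycline turns on an Etv2 cassette. They were differentiated as embryoid bodies, and Flk1-positive cells were sorted at day 3.5. Flk1 is the protein of the gene Kdr. The sort selects on that protein in both groups, so a comparison of Kdr between the groups is a check of the gate and not a finding.

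Groups were taken from the sample titles, which name 3 controls and 3 doxycycline inductions. The treatment field carries the same doxycycline text on all 6 samples, while the series' design text calls the controls untreated. The design text speaks of an experiment in triplicate, and no label says whether the replicates were separate cultures. The p-values therefore measure the spread between these samples, which may be partly technical.

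The deposited table holds log2 expression values per probe set, which the authors made with RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes the arrays and summarises the probes of each probe set. The version, the probe annotation and the software used for it are not given in the sources used here. The scanner files were not used here, so background correction and detection calls could not be varied. The table holds 45101 probe sets, and the array medians lay between 7.34 and 7.40. The number of arrays, 3 per group, limits the precision.

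Probe sets were named through the GEO platform annotation supplied with the table. Of the 45101 probe sets, 35890 had an entry there. An entry with 1 gene symbol was found for 34958 and with several symbols for 932, while 9211 had no entry and stayed unnamed. After 13 Affymetrix control probe sets with a symbol were set aside, 34945 probe sets were used. The Entrez identifiers of 34754 of the probe sets with 1 symbol were found in NCBI RefSeq (GRCm38.p6), and 0 symbols changed. That gene table was otherwise used only for the order of neighbouring genes, since the build behind the array annotation is not given in the sources used here. Each of the 18193 genes was represented by the probe set with the highest mean over all 6 arrays. More than 1 probe set existed for 9010 genes. No filter on dim probe sets was applied.

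Induced and control samples were compared with limma (version 3.58.1 in R 4.3.3) by lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the 18193 genes and a threshold of 0.05. Every log2 fold change is induced minus control. Errors of fold changes are standard errors of the fit, and group means carry the SD. For 3 samples against 3, an exact permutation test has 20 assignments and a smallest two-sided p of 0.1, so it cannot pass 0.05. The median log2 fold change over all genes was 0.0026.

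The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The 25 lists held 393 genes, of which 382 were measured. They cover endothelial genes, haematopoietic regulators, primitive erythroid genes, macrophage genes, ETS factors, the Notch pathway, cardiac mesoderm, primitive streak mesoderm, paraxial mesoderm, pluripotency, definitive endoderm, visceral endoderm, neuroectoderm, mural and smooth muscle genes, fibroblast genes, epithelial and mesenchymal genes, the cell cycle, p53 targets, ATF4 and mitochondrial stress genes, immediate-early genes, hypoxia and glycolysis, BMP targets, FGF and MAPK targets, and Wnt targets. The remaining list is counted in the totals and not reported here. List shifts were tested with camera at a preset correlation of 0.01, which compares the members with all other genes. Camera with the correlation estimated from the data, and fry, which asks whether members move one way on balance, were the alternatives.

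The genes named are Etv2, Lmo2 and Kdr in every case. Added to them are up to 12 largest rises and 12 largest falls among genes past the threshold with non-overlapping groups, leaving out clone names. From each list up to 5 members past the threshold are named, or, in a list with none, the 2 members with the highest level. The 2 members with the highest level are also named for visceral endoderm, fibroblasts, neuroectoderm, pluripotency and macrophages. Any other gene is said to have been chosen after its values were seen.

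The replicate numbers in the titles are shared by both groups. Deviations from the group means correlated over genes at r = 0.16 for number 1, r = 0.22 for number 2 and r = 0.41 for number 3. All 3 exceed 0.1, the level set for treating the numbers as pairs. The pairing therefore rests on the data and the shared numbers, and no label gives a shared day or culture. Not every sample correlated best with its own number, since control 2 and induced 1 reached r = 0.30 and control 1 and induced 3 reached r = 0.24. The reported comparison has no pair term, and the fit with the replicate number as a block is given where it changes a call. Its standard errors thus include differences between the numbers, as for Kdr, at 0.59 against 0.26 with the block. For other genes the block made the error slightly larger, as for Epor, at 0.094 against 0.10.

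The steps were tested on simulated data with the 18193 genes and independent residuals, in 10 runs. Of genes changed 1.5-fold, 55.6% were recovered, rising to 85.4% at 2-fold, 98.8% at 4-fold and 99.6% at 8-fold, with a false share of 4.66%. Over the 10 runs 500 genes were changed at each size, and many true changes ease the Benjamini-Hochberg threshold. These shares therefore do not carry over to the real comparison, where 1 gene was called. There Etv2, at 11.8-fold, missed the threshold (limma adjusted p = 0.388). A simulated shift of 0.1 in the endothelial list was called in 19 of 20 runs with the preset correlation and in 0 of 20 with the estimated correlation. At 0.3 both called it in 20 of 20. Other planned settings were quantile normalization, centring on the array median, genes above the median level, other probe set choices, another variance model, array weights, a test against a 1.5-fold change, each probe set tested on its own, and each sample left out. The planned change of pseudocount was not run, because the values are already on the log2 scale.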

Results

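Gene expression was measured in Flk1-positive cells sorted from embryoid bodies, the aggregates that ES cells form as they differentiate. The ES cell line carried a cassette that makes Etv2 when doxycycline is added. Etv2 is an ETS-family transcription factor needed for the endothelial and blood lineages. Flk1, encoded by Kdr, is a VEGF receptor on early mesoderm from which those lineages arise. In 3 samples doxycycline at 0.5 microg/ml was given from day 3 of differentiation for 12 hours, and 3 untreated samples served as controls. All were collected at day 3.5, and the values are log2 RMA expression levels of 18193 genes.

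The comparison asks which genes differ after 12 hours of Etv2 induction. No doxycycline-treated line without the Etv2 cassette was analysed here. For every gene and list, an effect of doxycycline itself therefore cannot be told apart from one of Etv2. Etv2 itself stood at 13.30 ± 0.048 (SD, n = 3) in the induced samples and at 9.74 ± 1.07 in the controls. The log2 fold change was 3.56 ± 0.44 (SE), or 11.8-fold, with a 95% interval of 2.54 to 4.59, and all 3 induced samples lay above all 3 controls. Whether the Etv2 probe set reads the cassette's transcript, the endogenous transcript or both is not given in the sources used here, so the fold change does not separate them. The control levels of Etv2 were spread widely, at 9.92, 8.59 and 10.71 in replicates 1, 2 and 3, while the induced levels were 13.27, 13.28 and 13.36. Against that control spread, limma gave Etv2 an adjusted p of 0.388, and an exact permutation test of the 3 against 3 values gave p = 0.1, the smallest it can give. Leaving out control 2 brought the Etv2 log2 fold change to 2.99 and its adjusted p to 0.0055.

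Hprt, an X-linked gene for an enzyme of purine salvage, was the gene that rose past the adjusted threshold. Its level was 9.96 ± 0.17 (SD, n = 3) in induced samples and 8.40 ± 0.097 in controls. The log2 fold change was 1.57 ± 0.10 (SE), or 2.96-fold, with limma's adjusted p at 0.0071, and it was higher in 3 of 3 induced samples. No gene fell past the adjusted threshold in limma, with or without the replicate number as a block. At an unadjusted p under 0.05 there were 312 genes, 158 of them lower, and 655 with the block, 396 of them lower, where chance alone would give 909.65. The call for Hprt was lost without control 1, induced 1 or control 3 (adjusted p = 0.123, 0.0816 and 0.0642), and without both samples of replicate 1 or replicate 3 (0.9999 and 0.127), while its log2 fold change stayed between 1.48 and 1.65 over all settings tried.

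**Figure D1:**
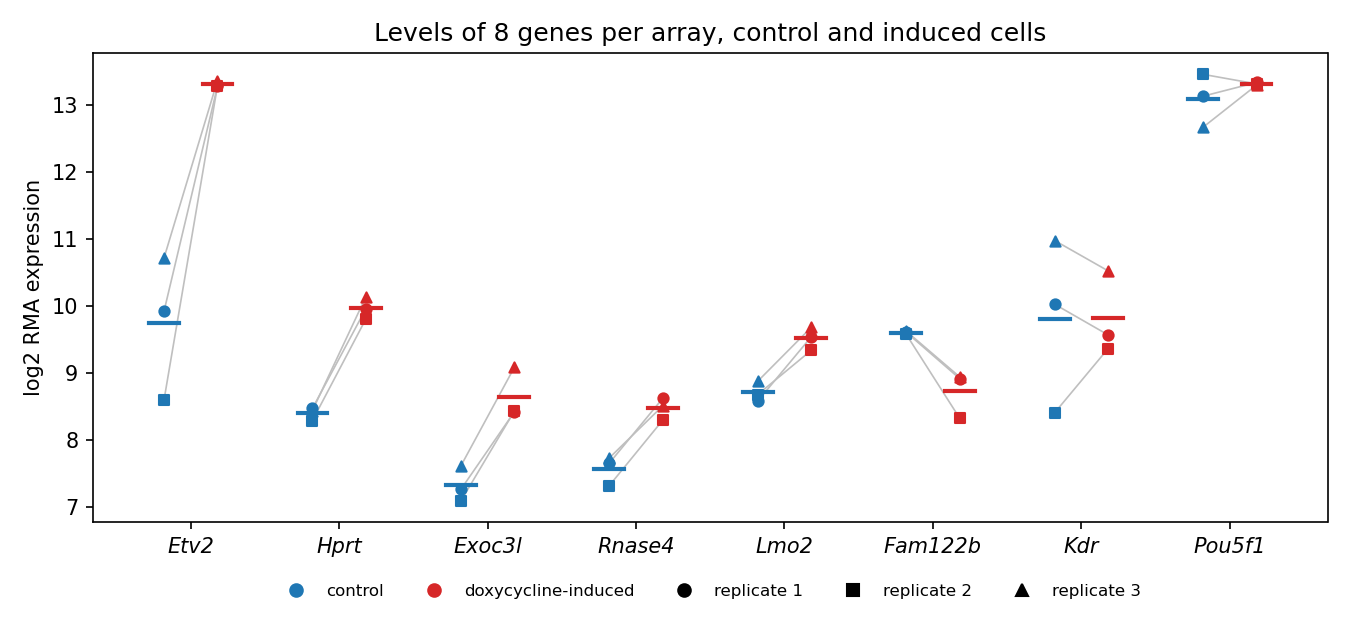
Log2 RMA levels of Etv2, Hprt, Exoc3l, Rnase4, Lmo2, Fam122b, Kdr and Pou5f1 in each array, with controls in blue and induced samples in red. Marker shapes give the replicate number, grey lines join samples of a number, and thick bars are group means; induced Etv2 lies between 13.27 and 13.36, while Kdr overlaps between the groups.

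Lmo2, a LIM-domain cofactor of blood and endothelial transcription factors, was named beforehand because it has been studied as an Etv2 target. It stood at 9.52 ± 0.17 (SD, n = 3) in induced samples and 8.71 ± 0.15 in controls, a log2 fold change of 0.81 ± 0.12 (SE) or 1.75-fold, and was higher in 3 of 3. Over all genes limma's adjusted p was 0.389, and adjusted over the list alone, among the haematopoietic regulators, it was 0.0025. Having been chosen for that earlier work, Lmo2 is not independent evidence of the list's direction. Kdr, the gate's own gene, was at 9.82 ± 0.62 in induced samples and 9.80 ± 1.30 in controls, a log2 fold change of 0.016 ± 0.59.

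Several genes outside the naming rule, chosen after their values were seen, lay wholly above the controls in the 3 induced samples without passing the threshold in limma. Exoc3l had a log2 fold change of 1.32 ± 0.20 (SE), from 7.32 to 8.64, with an adjusted p of 0.418. With the replicate number as a block it passed at an adjusted p of 0.0135, which made 2 genes changed in that fit. Nt5e, a cell-surface enzyme that produces adenosine, had a log2 fold change of 1.13 ± 0.32. With Etv2, Hprt and Exoc3l it made up the 4 genes at least 2-fold apart whatever the p, all of them higher. Rnase4, a secreted ribonuclease, had 0.91 ± 0.13, Slc39a4, a zinc importer, 0.84 ± 0.11, and Ltb, a cytokine of the tumour necrosis factor family, 0.80 ± 0.11. On the lower side, Fam122b had a log2 fold change of -0.88 ± 0.16 and Ccnb1ip1 of -0.57 ± 0.086. Non-overlapping groups were seen in 1236 genes, or 6.79%, where chance gives 10%, with 524 higher and 712 lower.

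Endothelial genes lay higher as a group in the induced samples. Of 34 measured members 27 had a positive log2 fold change, with a mean of 0.099 and a camera adjusted p of 1.63e-04. The call was lost with the correlation estimated from the data (adjusted p = 0.860 with an estimated correlation), and 0 members passed limma's threshold singly, with 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The members with the smallest p, chosen after their values were seen, were Rhoj, with a log2 fold change of 0.33 ± 0.091 (SE), and Ecscr, a surface protein of endothelial cells, with 0.36 ± 0.10. The 2 members with the highest level were the apelin receptor gene Aplnr, at 12.83 in controls and 12.79 in induced samples, and Egfl7, at 10.16 and 10.15. Cdh5, which encodes VE-cadherin and was also picked after its values were seen, stood low, at 6.25 in controls and 6.44 in induced samples. Only 6 of the 34 members lay above the median level of all genes, and among genes above that median the list was not shifted (adjusted p = 0.615). Induced 2 stood apart from the other arrays, with a median of 7.40 against 7.34 to 7.35 and a lower quartile of 6.06 against 5.96 to 6.003. Camera at the preset correlation kept the call after quantile normalization, with a mean of 0.085 (adjusted p = 0.0068). The call was also kept after each array was centred on its median, at 0.081 (adjusted p = 9.45e-05). In pairs 1, 2 and 3 the list's mean was higher by 0.072, 0.21 and 0.013. The list's mean was 0.082 without induced 2 (adjusted p = 0.0175), 0.059 without control 2 (adjusted p = 0.0108), and 0.043 without both samples of replicate 2, a setting chosen after the data were seen (adjusted p = 0.0681).

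Haematopoietic regulators were the other list that was shifted upwards. Positive log2 fold changes were found in 16 of 21 members, with a mean of 0.105, a median of 0.102 and a camera adjusted p of 0.0052. Lmo2, at 0.81, is one of these members, and the list was not tested without it. This call too was lost with the correlation estimated (adjusted p = 0.860 with an estimated correlation), and Lmo2 alone passed when adjusted over the list alone. Kit, a receptor of blood progenitors, had a log2 fold change of 0.11 ± 0.13 (SE), and Gata2, a transcription factor of the same cells, 0.13 ± 0.27. The list's adjusted p was 0.0827 without control 1, 0.0668 without control 2, 0.137 without induced 2 and 0.0566 with the most variable probe set of each gene. Without both samples of replicate 2 its mean was 0.056 and its adjusted p 0.415. Fry, which asks only whether members move one way on balance, called 0 of the 25 lists.

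The remaining blood lists, ETS factors and the Notch list were not shifted by camera. Primitive erythroid genes were split 6 and 6 (adjusted p = 0.665), with the transferrin receptor gene Tfrc at a log2 fold change of -0.19 ± 0.12 (SE) and the erythropoietin receptor gene Epor at 0.0087 ± 0.094. Among macrophage genes 10 of 12 were positive (adjusted p = 0.302), with Coro1a at 0.23 ± 0.25 and Laptm5 at 0.050 ± 0.10. ETS factors other than Etv2 were negative in 13 of 19 (adjusted p = 0.665), with Etv5 at -0.065 ± 0.075 and Gabpa at -0.0054 ± 0.081. The Notch pathway list was split 8 and 9 (adjusted p = 0.918), with Jag1 at -0.18 ± 0.24 and Notch3 at 0.040 ± 0.12. Single samples decided some of these results. The adjusted p was 0.0254 for erythroid genes (lower) without induced 2 and 0.0401 for macrophage genes (higher) without induced 1. It was 0.0498 for the Notch list (lower) without control 2. Each of these calls comes from camera at the preset correlation of 0.01, and the estimated correlation was not used there. Over all 6 samples the estimates were 0.453 for erythroid genes, 0.330 for macrophage genes and 0.0155 for the Notch list.

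Mesoderm lists were not shifted between the groups, while their members varied between samples of a group. Primitive streak genes were negative in 13 of 19 (camera adjusted p = 0.398), paraxial mesoderm genes in 10 of 14 (0.839) and cardiac mesoderm genes in 11 of 20 (0.939). The T-box gene Eomes stood at 13.53 in controls and 13.43 in induced samples, and the homeobox gene Mixl1 at 13.47 and 13.48. The Wnt effector gene Lef1 was at 11.29 and 11.19, the Notch ligand gene Dll3 at 11.00 and 10.94, the GATA factor gene Gata6 at 10.64 and 10.66, and the actin gene Actc1 at 9.87 and 9.92. In the controls the SD was 0.94 for Dll3 and 0.92 for Gata6, against 0.33 and 0.35 in the induced samples. The mean level of the 53 mesoderm genes was 8.90, 8.29 and 9.04 in controls 1, 2 and 3 and 8.60, 8.57 and 8.86 in induced samples 1, 2 and 3. Without control 2 the 3 lists were shifted downwards, with a mean log2 fold change of -0.32 for primitive streak (adjusted p = 1.22e-07), -0.28 for paraxial (0.0023) and -0.28 for cardiac mesoderm (4.22e-04). These calls come from camera at the preset correlation of 0.01, and the estimated correlation was not used with samples left out. Over all 6 samples the estimates for these lists were 0.344, 0.221 and 0.477. The leading principal component held 44.8% of the variance and did not separate the groups.

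**Figure D2:**
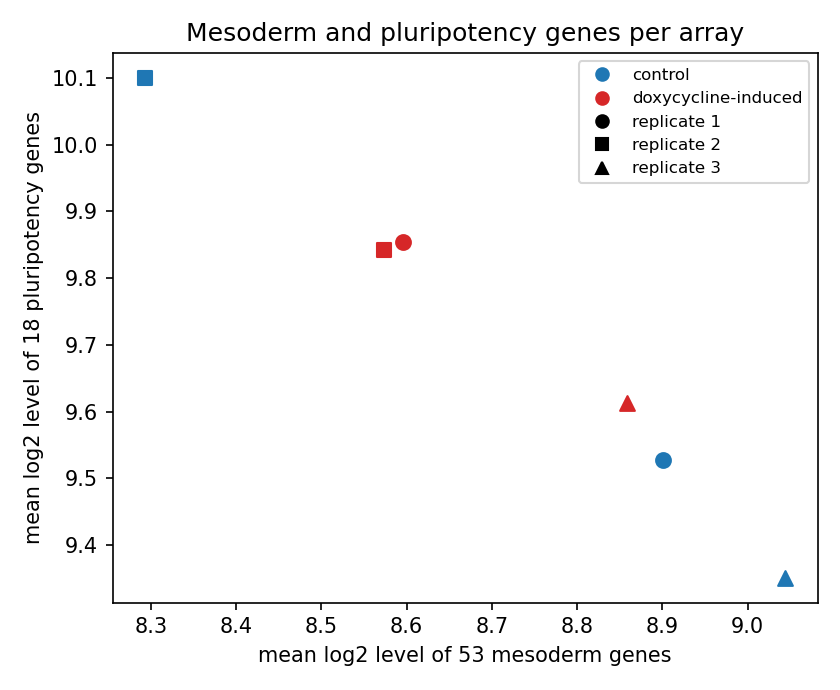
Mean log2 RMA level of 53 mesoderm genes (horizontal) and of 18 pluripotency genes (vertical) in each of the 6 arrays, controls in blue and induced samples in red, with marker shapes for the replicate number. Control 2 has the lowest mesoderm mean, 8.29, and control 3 the highest, 9.04, with the 3 induced samples between them.

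The 2 pluripotency genes with the highest levels stood high in both groups of Flk1-positive cells. Tdgf1, a Nodal co-receptor gene, stood at 13.73 ± 0.13 (SD, n = 3) in controls and 13.75 ± 0.090 in induced samples, and Pou5f1, which encodes Oct4, at 13.08 ± 0.40 and 13.31 ± 0.020. The list was positive in 13 of 18 members, with a mean log2 fold change of 0.11 and a camera adjusted p of 0.380. Without control 2 its mean was 0.33 at an adjusted p of 1.22e-07, and among genes above the median level the adjusted p was 0.0164. Both calls come from camera with the preset correlation, and the estimated correlation was not used in these 2 settings. In the comparison of all 6 samples the estimate was 0.268, with a camera adjusted p of 0.952. Over the 6 samples the pluripotency mean ran against the mesoderm mean (Pearson r = -0.994, exact permutation p = 0.0028, adjusted 0.00625; Spearman rho = -0.943, p = 0.0167, adjusted 0.025), as 1 of 3 relations computed. Without the 2 samples farthest from the median of the mesoderm mean, r was -0.990. Kdr varied between sorted samples of a group, from 8.40 to 10.97 in the controls, and was related to the mesoderm mean (r = 0.970, exact permutation p = 0.0042, adjusted 0.00625; rho = 0.943, p = 0.0167, adjusted 0.025), with r = 0.868 without the 2 samples farthest in Kdr.

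Markers of other lineages that an embryoid body could hold were not shifted. Definitive endoderm genes were positive in 8 of 11 (camera adjusted p = 0.398), with Epcam at 12.52 in controls and 12.58 in induced samples and Trh at 12.40 and 12.43. Visceral endoderm genes were positive in 10 of 13 (0.164), with the lipoprotein gene Apoe at 10.95 and 11.36 and Ttr at 8.90 and 8.96. Neuroectoderm genes were split 7 and 6 (0.918), with Otx2 at 12.23 and 12.16 and Sox11 at 12.14 and 12.20. Mural and smooth muscle genes were split 5 and 7 (0.672), with Tagln at 11.13 and 11.43 and Cnn1 at 8.96 and 8.87. Fibroblast genes were split 6 and 6 (0.964), with Mmp2 at 9.98 and 9.85 and Col5a1 at 8.81 and 8.73. Epithelial and mesenchymal genes were positive in 10 of 13 (0.398), with the E-cadherin gene Cdh1 at 13.22 and 13.34 and the fibronectin gene Fn1 at 13.54 and 13.64. With the mesoderm mean as a covariate, a fit added after the data were seen, this last list was higher at an adjusted p of 0.0091, which was lost with the correlation estimated (adjusted p = 0.709 with an estimated correlation).

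Proliferation and stress lists were not shifted. The cell cycle list was split 10 and 11 (camera adjusted p = 0.862), with the replication genes Pcna at a log2 fold change of -0.039 ± 0.070 (SE) and Mcm7 at -0.054 ± 0.073. The p53 target list was split 7 and 6 (0.923), with Trp53inp1 at 0.011 ± 0.11 and Ccng1 at -0.0045 ± 0.17. ATF4 and mitochondrial stress genes were split 7 and 8 (0.923), with Atf4 at -0.044 ± 0.082 and Phgdh at -0.076 ± 0.096. Hypoxia and glycolysis genes were positive in 5 of 14 (0.665), with Ldha at -0.054 ± 0.078 and Aldoa at -0.039 ± 0.073. Immediate-early genes were positive in 6 of 14 (0.665), with Ier2 at 0.0095 ± 0.099 and Egr1 at -0.47 ± 0.17.

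The BMP, FGF and Wnt target lists were likewise not shifted. BMP targets were split 5 and 6 (camera adjusted p = 0.918), with Id1 at a log2 fold change of -0.073 ± 0.19 (SE) and Id3 at 0.066 ± 0.16. FGF and MAPK targets were positive in 6 of 10 (0.571), with Dusp6 at 0.0014 ± 0.085 and Spry2 at 0.095 ± 0.11. Wnt targets were positive in 4 of 10 (0.862), with Cyp26a1 at -0.092 ± 0.43 and Tcf7l1 at -0.044 ± 0.078. Without induced 2, camera at the preset correlation gave an adjusted p of 0.0457 for FGF and MAPK targets, which were then higher.

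Over all lists, 0 of the 382 measured members passed limma's threshold over all genes, and 1, Lmo2, passed when adjusted over the list alone. With the replicate number as a block, 7 passed when adjusted over the list alone, 6 of them in that fit only and chosen here after their values were seen. Of these 6, 5 are named here: levels were higher for the ETS factor Elk3 (log2 fold change 0.78, adjusted p = 0.0142), the forkhead factor Foxa1 (0.41, 0.0314) and the Wnt target Apcdd1 (0.39, 0.0277), and lower for the Nodal antagonist Lefty2 (-0.57, 0.0182) and the immediate-early gene Egr1 (-0.47, 0.0160).

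Hprt lies on the X chromosome, and the 12 measured genes nearest to it in the RefSeq order were examined after its rise was seen. Of these 9 had a negative log2 fold change, the largest being -0.88 for Fam122b, -0.50 for Ccdc160, -0.31 for Gpc3, -0.29 for Phf6 and -0.29 for Mospd1. None of the 12 passed limma's threshold over all genes, and 2 had induced samples wholly below the controls.

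**Figure D3:**
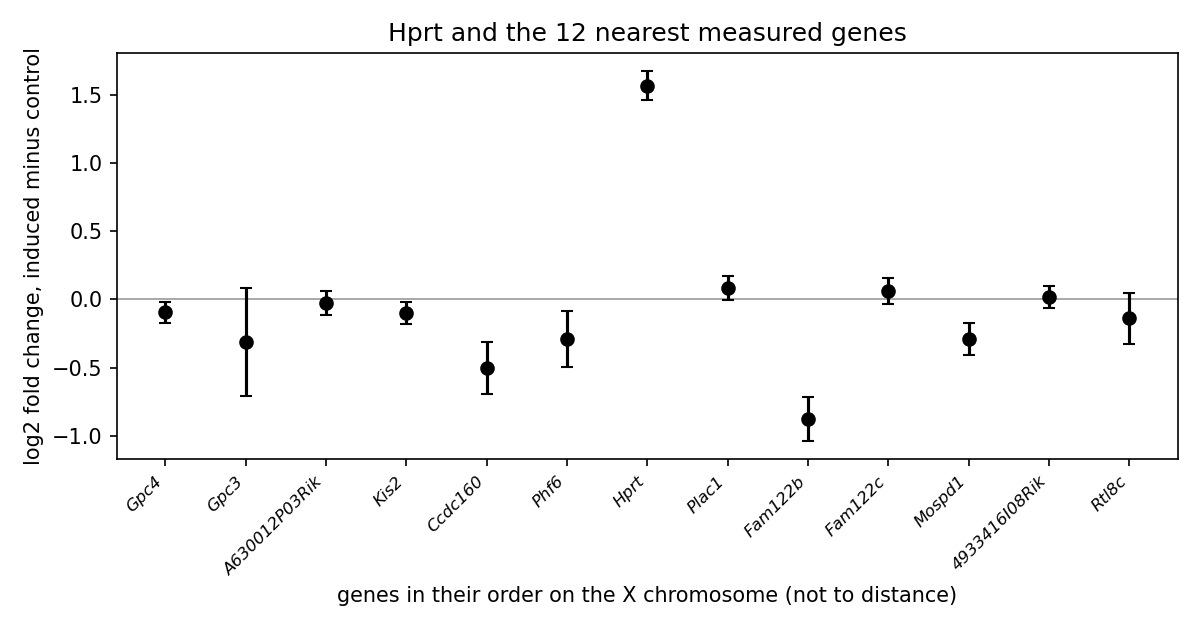
Log2 fold change, induced minus control, of Hprt and of 6 measured genes on each side of it, placed in their order on the X chromosome and not to distance, with standard errors of the limma fit as bars. Hprt stands at 1.57 and Fam122b at -0.88.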

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

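Array levels of dim genes are compressed by background, which limits a small shift in a list of mostly dim genes. Settings that leave out both samples of a number, use the mesoderm mean as a covariate, or join the estimated correlation to the block or to that covariate were chosen after the data were seen. With the replicate block 2 genes changed, 2 of them higher and 2 at least 2-fold, against 1, 1 and 1; Etv2 stayed at 3.56 (adjusted p = 0.0546) and Lmo2 at 0.81, and the block ended or added no other call over all genes and kept both lists. Array quality weights gave 6 genes changed, 6 higher and 2 at least 2-fold, with Etv2 called at 3.58 and Lmo2 at 0.93, both at an adjusted p of 0.0456. The mesoderm covariate gave 5 genes changed, 5 higher and 3 at least 2-fold, with Etv2 at 3.73 (adjusted p = 1.07e-04), and 4 lists. The test against a 1.5-fold change gave 0 genes. The most variable probe set of each gene left 1 list, and the estimated correlation, fry, and the estimated correlation with the block or the covariate left 0 each. Leaving out samples, singly or by number, gave 0 to 3 genes changed and 0 to 3 higher, 0 to 2 at least 2-fold, 1 to 6 lists, a log2 fold change of 2.99 to 4.05 for Etv2 and of 0.73 to 0.90 for Lmo2. No gene was called with control 1, induced 1 or control 3 left out, 3 were called without control 2, and fewer samples are part of each such setting. The cause was not tested for the others. The number of lower genes was 0 in each setting run. Hprt kept its call in 13 of 18 alternatives, the endothelial list in 16 of 22 and the haematopoietic list in 13 of 22. The other genes and lists followed had no call, and 12 values of genes and 19 of lists gained one. None reversed a called direction, while 150 gene and 80 list values without a call changed sign. The planned change of pseudocount was not run.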

Other observations

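The tests of the Hprt region, of members moving together and of the mesodermal share, with its covariate, were chosen only after the results were seen. The spread among the controls ran along genes of early mesoderm. Mesp1, a mesoderm transcription factor picked after its values were seen, stood at 12.92, 11.30 and 13.05 in controls 1, 2 and 3, and at 12.04, 11.85 and 12.61 in induced samples 1, 2 and 3. The retinoic acid-degrading enzyme gene Cyp26a1 stood at 12.76, 11.31 and 13.03 in controls 1, 2 and 3. Trh, from the definitive endoderm list, ran the other way, at 12.26, 13.53 and 11.40. Both varied more among the controls, with SDs of 0.93 for Cyp26a1 and 1.07 for Trh, than among the induced samples, with 0.49 and 0.59. Etv2 in the controls, at 9.92, 8.59 and 10.71, stood in the same order as Kdr, at 10.02, 8.40 and 10.97, which 3 values cannot test. With the mesoderm mean as a covariate, 5 genes passed limma's threshold, namely Etv2, Hprt, Exoc3l, Rnase4 and Slc39a4 (adjusted p = 1.07e-04, 3.49e-04, 0.0268, 0.0306 and 0.0329). The mesoderm mean was measured after induction, so this covariate could take out part of an effect of Etv2.

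Hprt was higher in every induced sample while its nearest measured neighbours were mostly lower. A general rise of housekeeping genes was argued against by 7 measured reference genes, of 10 set down beforehand, whose median log2 fold change was 0.000229 with an SD of 0.108, against 1.57 for Hprt. A candidate explanation is a local effect of the inducible cassette, which in lines of this A2Lox.cre type is placed beside Hprt. The mean absolute log2 fold change of the 12 neighbours was 0.234, at percentile 99.87 of 17893 windows of 12 genes, against a window median of 0.0811, and was 0.175 without Fam122b. This measure ignores sign and spread, so variable genes raise it, such as Gpc3 at -0.31 ± 0.40 (SE). As 9 of the 12 neighbours were lower, it does not show that they share the cause of the rise in Hprt. An action of Etv2 or of doxycycline on the region stays open, since no doxycycline-treated line without the Etv2 cassette was analysed here.

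Endothelial and haematopoietic genes lay slightly higher in the induced samples. A general shift of dim probe sets was examined with 10000 random lists matched on level. Among them the endothelial mean was at percentile 99.93 and the haematopoietic mean at 99.79. The random lists themselves rose by 0.027 and 0.014 on average, less than the observed 0.099 and 0.105. A shift common to genes of that level was thus smaller on average than the observed means. The percentiles cannot tell how rare the remainder is. Genes drawn at random lack the correlation among list members, which makes the random spread too narrow. Among genes above the median level camera did not call the endothelial list (adjusted p = 0.615) but called the haematopoietic list (adjusted p = 0.0123). A larger share of mesodermal cells stays open as a cause for both lists. The endothelial mean shift was 0.099 ± 0.052 (SE over samples), and 0.110 ± 0.038 with the mesoderm mean as a covariate. Camera then gave an adjusted p of 8.52e-06 (adjusted p = 0.709 with an estimated correlation). The haematopoietic shift with the covariate was 0.111 ± 0.063 (camera adjusted p = 0.0039, or adjusted p = 0.709 with an estimated correlation). Only the endothelial list met the bound of 2 standard errors, which is loose with 3 residual degrees of freedom. The covariate cannot decide, because the mesoderm mean was itself lower in induced samples (-0.0704). Adjusting for it raised both shifts. A reduction would have needed lists that run against the mesoderm mean within groups, the opposite of what a mesodermal share would give. Without control 2 the endothelial list stayed higher (0.059, adjusted p = 0.0108) while the mesoderm lists were lower. They were also lower without both samples of replicate 2, where the endothelial mean was 0.043 and its call was lost (adjusted p = 0.0681). Pair 2 had the largest endothelial difference (0.21, against 0.072 and 0.013 in pairs 1 and 3) and was the pair with higher mesoderm genes (0.28, against -0.31 and -0.19). The test set beforehand, a mesoderm mean (-0.0704) below the endothelial mean by over 2 standard errors, was met over genes (0.169 ± 0.030), which are not independent, and not over pairs (0.169 ± 0.13), so the covariate replaced it. Members moving together between samples of a group also stays open, because the loss of the endothelial call with the correlation estimated (adjusted p = 0.860) decides nothing when that test found a simulated shift of 0.1 on independent residuals in 0 of 20 runs. The estimated correlations among members were 0.106 for the endothelial and 0.245 for the haematopoietic list, above the preset 0.01, as that explanation would give. Camera with the preset called at least as many lists in 9 of the 10 splits of the 6 samples, real split included. Its adjusted p-values for these 2 lists may therefore be too small. For the endothelial list alone, the unadjusted camera p was 6.51e-06 in the real split, the smallest of the 10. The next smallest was 9.21e-04, and 10 splits are too few for a share under 0.05. An early response of these genes to Etv2 is the biological explanation the design names, and it stays open as well. An effect of doxycycline itself cannot be told apart from it.

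Mesoderm genes differed between samples of the same group. Different shares of mesodermal and less differentiated cells in the sorted samples may underlie this, since the mesoderm and pluripotency means were related at r = -0.994, while a difference in stage among all cells would give the same relation. The Flk1 sort would remove most Flk1-negative cells, so such a share needs less differentiated cells that passed the gate, which was not tested. RNA or array quality, read from the 18S control probe sets, is not excluded. The 18S level was related to the mesoderm mean at r = -0.159 (exact permutation p = 0.764, adjusted 0.764; rho = 0.029, p = 1.00, adjusted 1.00), but at r = 0.754 without the 2 samples farthest in 18S. The bound set beforehand, an absolute r below 0.2, was thus met only with those samples, which is too weak at 6 samples to exclude it. The replicate numbers follow this spread, since in both groups the mesoderm mean and Kdr were lowest in number 2 and highest in number 3. What the numbers share is not given in the labels, and no biological explanation of the spread was tested.

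Control 3 had the lowest 18S level, 10.33, against 11.25 to 13.79 in the others, and the widest gap between the 3' and 5' actin probe sets, 0.605. For the comparison of the groups, the 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1 gene and 2 lists, and the highest of the others gave 40 genes and 10 lists. At least as many genes came from 2 of the 10 splits, and at least as many lists from 9. The split with 40 genes set control 1, control 3 and induced 3 against the rest, which are the 3 samples with the highest mesoderm means, and so points to that structure of the samples; it parts 1 replicate pair. Of the 4 splits that part all 3 pairs, the real split gave 1 gene and the others 0 genes, with up to 6 lists. Among the 10156 probe sets left out of the gene comparison, 0 passed limma's adjusted threshold and 143 had an unadjusted p under 0.05.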
